A study of Homo sapiens with 20 samples.

How the data were processed

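The series holds 20 ChIP-seq libraries from HCT116, an established human colorectal carcinoma cell line, grown as wild type (WT) or as an MLL4 knockout (KO). MLL4, encoded by KMT2D, is a histone H3 lysine 4 methyltransferase linked to enhancers. Per the labels, 6 targets were immunoprecipitated in both genotypes. H3K4me3, H3K27ac and p53 had 2 libraries per genotype, and H3K4me1, MLL4 and MLL1 had 1. The remaining 2 libraries were inputs, 1 per genotype, whose own values were not analysed here. Per the labels' protocols, cells were crosslinked with 1% paraformaldehyde for 5 min and sonicated for 15 min, and libraries made with an NEBNext Ultra II kit were sequenced on a NovaSeq X Plus. The labels name no treatment that activates p53. They also do not say that replicates came from separate cultures, so a p-value for peak numbers measures only the spread between these libraries, which may be technical.

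The data used were 18 peak lists, 1 per ChIP library. Peaks were called with MACS2 2.1.1 on the hg38 build, per the submitters' processing notes. The peak names inside the deposited lists show that each library was called on its own against the input of its genotype, with no pooling of replicates, so all lists of a genotype share 1 input. The aligner, read filters and read depth are not given in the sources used here. For each peak the authors' lists give the fold enrichment, a ratio of ChIP over local background, and the −log10 p-value and −log10 q-value of that enrichment. The deposited score is a whole number equal to 10 times the −log10 q-value within a difference of 1. The lowest −log10 q-value in the authors' narrow lists lay near 1.3 (q of 0.05), apart from 1.55 in the short MLL4 list of KO, and in the H3K4me1 lists, which are broad, near 1 (q of 0.1). Fold enrichment and scores are the authors' own values per peak, and they were used to describe, rank or filter peaks, to stratify regions by WT fold and to recover the background level of a list. They were set side by side between libraries without a test.

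Peaks on chromosomes 1 to 22 and X were kept. Peaks on Y, the mitochondrial genome and unplaced sequences entered no comparison. For each target, the peaks of all its libraries were merged into regions where they overlapped by at least 1 bp, and a region was called in a library if 1 of its peaks lay in it. WT-only (lost) regions were called in every WT library and in no KO library, KO-only (gained) regions the reverse, and retained regions in every library. A region was bound by MLL4 if it overlapped an MLL4 peak of the WT library, and bound by p53 if it overlapped a p53 region called in both WT p53 libraries. Because presence of a called peak was the measurement, a lost region is one that fell below the calling limit, and no change in occupancy above that limit could be seen.

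The gene table used, RefSeq on GRCh38.p14, which is the build of the peak lists, gives no strand. Promoter regions were therefore those within 1 kb of either end of a protein-coding gene, in place of the transcription start that the design named, and all other regions were distal. Regions were assigned to the protein-coding gene with the nearest end up to 100 kb away, out of 19974 such genes. The design also named a search for p53 response elements, which needs a genome sequence and was not run.

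Peak numbers were compared with a two-sided exact permutation test of log2 peak number. With 2 libraries against 2 its smallest p is 0.333, and no test was made with 1 library per genotype. For the replicated targets, WT-only and KO-only counts were set beside the counts for the other ways to divide the 4 libraries into pairs. Odds ratios compared WT-only with retained regions by Fisher's exact method with 95% intervals, and stratified values used the Mantel-Haenszel method. Shares have 95% Wilson intervals. All intervals cover counting error over regions only, and neighbouring regions are not independent. For 12 gene lists, the share of a list's regions that were lost or gained was compared with 10000 random lists of as many genes matched on regions per gene. For replicated targets this gave a two-sided permutation p with Benjamini-Hochberg adjustment over the 12 lists, and for the others only a percentile. These p-values measure spread over genes and not between libraries.

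The genes named in the text followed a rule: from each list, up to 4 members with the most WT-only and up to 2 with the most KO-only regions; for H3K4me1 and H3K27ac, the 10 genes with the most WT-only and the 5 with the most KO-only regions; for H3K4me3, p53 and MLL1, the 5 WT-only and 5 KO-only regions of highest fold enrichment; for MLL4 and p53, the 10 WT regions of highest −log10 q-value; and fixed genes, among them KMT2D, CDKN1A and MDM2, throughout. Some genes that the rule names are not reported here. The design, gene lists, this rule and the first set of alternatives were fixed before the data were examined. Those alternatives were a −log10 q-value of at least 5, lists of equal length for a target, at least 50% of a peak covered, promoters within 2.5 kb, genes up to 50 kb away, stratification by decile of WT fold enrichment, a replicate block and leaving out each replicate. Added after seeing the data were stratification by region width, by fold and width together and the same among regions without H3K4me3, regions merged over WT peaks alone with and without these stratifications, distal regions taken as those without H3K4me3, other divisions of the libraries for H3K27ac regions of at least 10-fold enrichment, the H3K27ac fold of KO over WT at retained regions with retained H3K4me3, leave-outs for the gene lists, and the background level behind each list. That level, in expected fragments per position, was recovered from the deposited fold enrichment and −log10 p-values under the MACS2 pseudocount of 1, and it is not a read total.

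The region calls were tested on simulated data. With 200 WT-only and 200 KO-only regions set among the 29149 retained H3K27ac regions and 5% random misses per library, 184 and 179 were recovered, against 180.5 of each left by the misses, and 118 other regions were called, against 129.7 set by the misses. For 15520 H3K4me3 regions 185 and 184 were recovered with 63 others, and for 14296 p53 regions 177 and 180 with 67. These simulations used retained regions and random misses alone, so they test the counting and not false calls at weak regions. The real lists differed more. Of H3K27ac regions of WT replicate 2, 57.1% were called in WT replicate 1, and of p53 regions of KO replicate 2, 33.9% in KO replicate 1. An odds ratio set to 3 came back as 2.86 (95% interval 2.68 to 3.04). Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.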

Results

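ChIP-seq peak lists were compared between wild-type (WT) and MLL4-knockout (KO) HCT116 cells, a human colorectal carcinoma line, for the histone marks H3K4me1, H3K27ac and H3K4me3, for the methyltransferases MLL4 (KMT2D) and MLL1 (KMT2A), and for the transcription factor p53. H3K4me1 marks enhancers and the flanks of promoters, H3K27ac active enhancers and promoters, and H3K4me3 promoters. H3K27ac, H3K4me3 and p53 had 2 libraries per genotype. H3K4me1, MLL4 and MLL1 had 1, so values for these 3 targets have no replicate check and no p-value. Lists held between 278 peaks (MLL4, KO) and 198757 peaks (H3K27ac, WT replicate 2) on chromosomes 1 to 22 and X. Read depth is unknown. Fold enrichments are the authors' own per peak, from calling each library on its own, and positions are on hg38. A region was taken as lost when it was called in every WT and no KO library, as gained in the reverse case, and as retained when called in all libraries of the target.

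**Figure D1:**
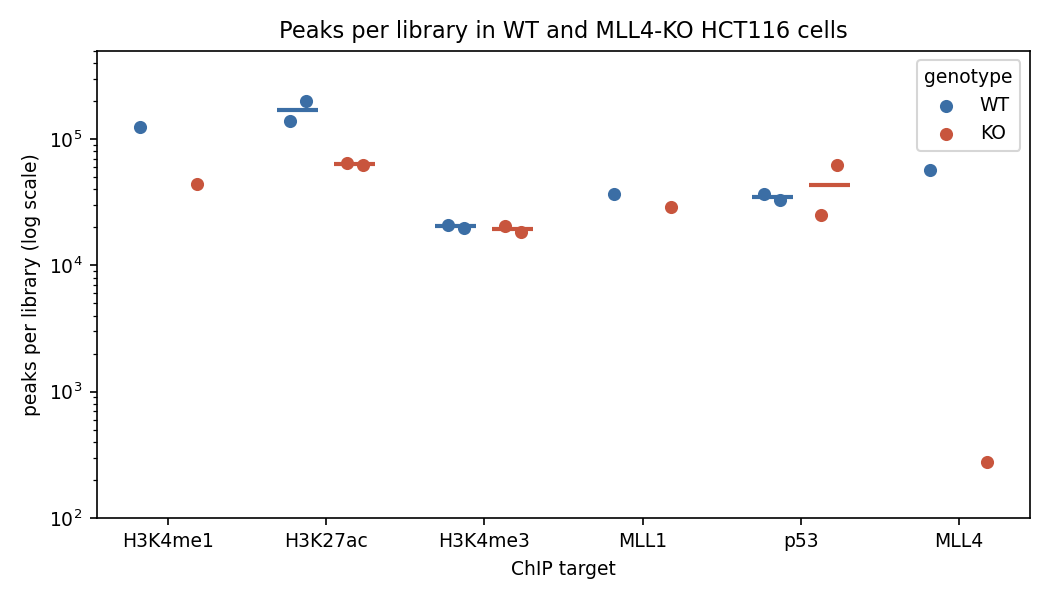
Each point is the number of peaks of 1 library on a log scale, by ChIP target and genotype, and bars are means where there were 2 libraries. MLL4 went from 56770 peaks in WT to 278 in KO, while H3K4me3 stayed between 18388 and 20922 peaks in all 4 libraries.

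MLL4 occupancy was read first, as the check on the knockout. The WT library held 56770 MLL4 peaks and the KO library 278, a 204-fold difference, and 155 of the WT peaks (0.273%, 95% interval 0.233 to 0.319) overlapped a KO peak. This overlap was 1.03% at −log10 q-values of at least 5, where log2 KO over WT peak number was −5.27 against −7.67 for all peaks, and 6.83% with lists of equal length. That threshold was reached by 8815 of the WT peaks and 229 of the KO peaks. The median fold of all WT peaks was 4.17. Most MLL4 peaks that define bound regions below were therefore weak. Among WT peaks, 47.6% overlapped an H3K27ac region called in both WT libraries, 37.2% an H3K4me1 peak, 21.9% a p53 region and 17.04% an H3K4me3 region. Of the KO peaks, 130 (46.8%, 41.0 to 52.6) overlapped a WT MLL4 peak, 9.71% lay at H3K27ac regions and 73.7% outside any histone peak of any library, against 43.0% of WT peaks for the last. At KMT2D itself an MLL4 peak of 5.84-fold lay 312 bp from a gene end (chromosome 12, 49060122 to 49060482). CDKN1A, which encodes the cell cycle inhibitor p21, had 6 MLL4 regions assigned in WT and MDM2, which encodes the ubiquitin ligase of p53, had 0; neither had any in KO.

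The strongest MLL4 peaks lay on genes of structural RNAs. Of the 10 WT regions with the highest −log10 q-values, 5 lay on chromosome 21 between 8207778 and 8443631, and 4 of these overlapped a ribosomal RNA gene. The other 5 lay on genes of short structural RNAs: RN7SL1 and RN7SL2, the RNA of the signal recognition particle (fold enrichment 530.3 and 288), the related pseudogene RN7SL4P in ANKRD28 (167), RN7SK, a regulator of transcription elongation (310.0), and RPPH1, the RNA of RNase P (139). The KO library had no MLL4 peak at any of these 5. The drop was not confined to MLL4. At all 5, MLL1 was lower in KO or not called there, as at RN7SL1 (87.0 in WT, 8.80 in KO). p53 was weak or not called at these genes, but it fell at a ribosomal RNA region on chromosome 21. Its folds there were 154 and 287 in WT and 26.5 and 43.2 in KO. The absence in KO therefore cannot show that these peaks are specific to MLL4. A background level of 0.199 expected fragments per position was recovered peak by peak for WT. The KO value of 1.71 came from the commonest p-values, of which it fitted 77.8%, so the levels are not compared.

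Fewer H3K4me1 peaks were called in the KO library across the genome. The WT list held 125507 peaks over 218 Mb and the KO list 43636 over 49.7 Mb, and log2 KO over WT peak number was −1.52, or −3.59 at −log10 q-values of at least 5. Of 125016 WT regions, 97104 (77.7%, 95% interval 77.4 to 77.9) were lost, and 8599 were gained. Genes with the most losses included EPHB2, a receptor tyrosine kinase of the intestinal crypt, which lost 47 of 50 assigned regions, GLI2, a transcription factor of Hedgehog signalling (45 of 53), LINGO1 (44 of 56), TSNARE1 (44 of 50), ARHGEF10L (43 of 46), CTIF (43 of 45), AGAP1 (42 of 49), PREX1 (42 of 46) and COL13A1 (41 of 49). Genes with the most gains included PPP2R2A (11 of its 13 KO regions), HUNK (9 of 11), ASPH (8 of 19) and EIF3H (7 of 12), and PPP2R2A lost 15 of 17 WT regions as well. Of the fixed genes, KMT2D lost 5 of 7 regions, CDKN1A 5 of 8 and MDM2 4 of 7. The broad H3K4me1 region over CDKN1A (chromosome 6, 36674132 to 36687118) was retained.

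The loss fell on regions away from promoters. Without an H3K4me3 peak, 93.7% of H3K4me1 regions were lost, against 13.9% with one. The odds of loss were 12.8 times higher at distal than at promoter regions (95% interval 12.3 to 13.2), and 92.2 times higher when distal meant no H3K4me3 peak. At equal WT fold enrichment and width, over regions merged from WT peaks alone, the value was 7.45. Among regions without H3K4me3 of equal WT fold enrichment and width the odds ratio was 1.09 (0.988 to 1.198), which no longer excluded 1. The widths in that comparison include KO peaks. With regions merged over WT peaks alone it was 1.23 (1.13 to 1.34). With lists of equal length, 23704 regions were WT-only and 17167 KO-only, so much of the excess of loss went with list length. The KO list was also weaker: 4161 of its 43636 peaks had a −log10 q-value of at least 5, against 50111 of 125507 in WT. Whether a weaker enrichment of the single KO library accounts for the H3K4me1 loss was not tested. At −log10 q-values of at least 5 the counts were 46744 and 525.

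Among the 12 gene lists, H3K4me1 loss was lowest, relative to random lists matched on regions per gene, for cholesterol and glycolysis genes (66.5% of regions, percentile 0.01), p53 targets (66.2%, percentile 0.03), cell cycle (62.6%, percentile 0.05), AP-1 and immediate early genes (71.6%, percentile 0.1) and housekeeping genes (59.2%, percentile 0.11). Hematopoietic markers stood highest (83.9%, percentile 99.8), with all 11 regions of IKZF1 and all 7 of CSF1R lost, followed by colon epithelium and Wnt genes (83.4%, percentile 95.9), where NKD1 lost 23 of 27 regions, ZNRF3 27 of 34 and AXIN2 22 of 25. HOX and MEIS genes stood at percentile 2.2 (64.2%), while H3K4 methyltransferase complexes (71.3%), interferon and NF-kB (70.5%), neuronal markers (76.6%) and the TGF-beta, EMT and mesenchyme list (81.1%) lay between percentiles 8.66 and 89.6. In H3K4me1 gain, AP-1 and immediate early genes stood below every random list (3 of 77 regions, percentile 0) and hematopoietic markers highest (9 of 23, percentile 96.7). These percentiles describe 1 library per genotype, and the random lists were not matched on fold enrichment or H3K4me3.

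**Figure D2:**
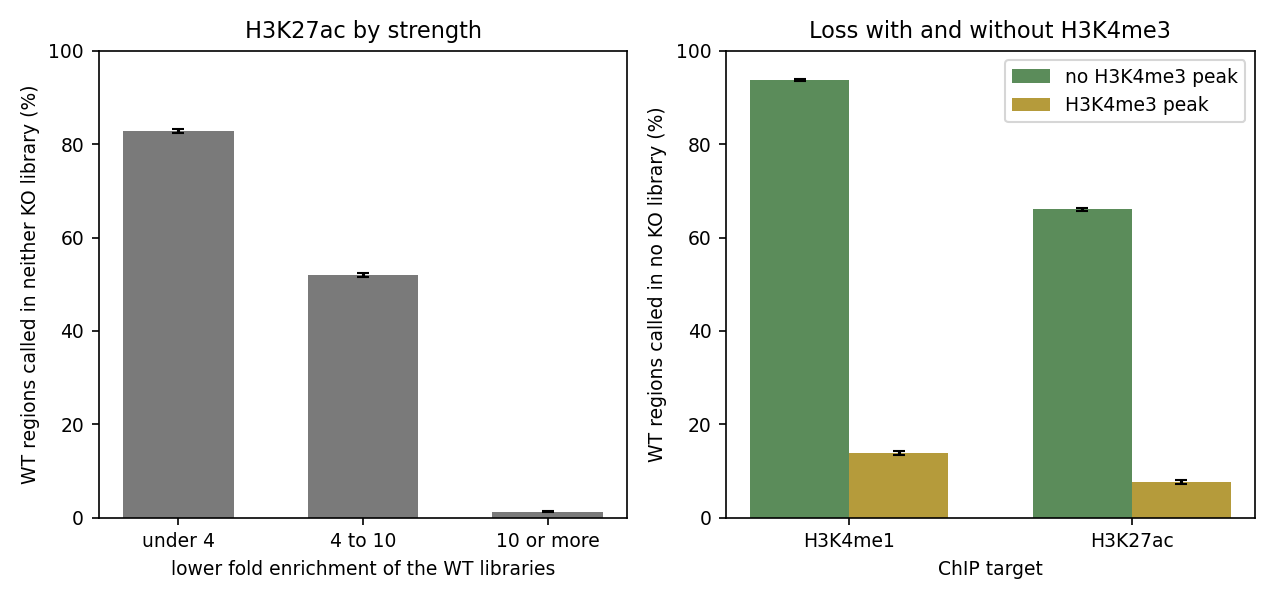
Bars give the percentage of WT regions not called in KO, with 95% Wilson intervals, by the lower WT fold enrichment of H3K27ac regions on the left and by overlap with an H3K4me3 peak on the right. H3K27ac loss went from 82.8% under 4-fold to 1.34% at 10-fold or more, and H3K4me1 loss was 93.7% without and 13.9% with H3K4me3.

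H3K27ac was lost from many weak distal regions and kept at strong ones. Losses were most numerous at ZMIZ1, a transcriptional coregulator (56 of 84 regions), EPHB2 (55 of 82), VAV2, a guanine nucleotide exchange factor (53 of 61), GLI2 (51 of 89), the collagen gene COL5A1 (50 of 59), CTIF (49 of 62), TSPAN9 (47 of 60), the chloride channel ANO1 (46 of 68), IQSEC1 (46 of 66) and ARHGEF10L (45 of 73), and none of these 10 had a gained region. Gains were few: LYPLAL1 had 10, PCDH7, a protocadherin, 7, and IFNE, SCG2 and ZC3H11B 6 each. CDKN1A lost 5 of 10 regions, KMT2D 6 of 12 and MDM2 1 of 2. The promoter regions of MDM2 (fold enrichment 140.1 and 132 in WT, 56.6 and 62.1 in KO) and KMT2D were retained.

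The H3K27ac lists held 168930 ± 42181 peaks in WT and 63504.5 ± 2186 in KO (SD, n = 2 each), over 176 ± 30.8 and 57.1 ± 7.75 Mb. Both KO libraries lay below both WT libraries, with an exact permutation p of 0.3333, the smallest this design allows. In all, 59066 regions, 55.2% of those in both WT libraries (95% interval 54.9 to 55.5), were lost and 1061 were gained; the largest count for another division of the 4 libraries was 2069. With lists of equal length the counts were 9233 and 2756, against 1861 for another division. At −log10 q-values of at least 5 they were 33227 and 418. A count with 1 library left out asks for fewer matching libraries. Without WT replicate 1, the shorter WT list, 140822 regions were lost. Gained regions numbered 2125 without WT replicate 1, 1740 without WT replicate 2, 6128 without KO replicate 1 and 4560 without KO replicate 2.

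Of regions with at least 10-fold enrichment in both WT libraries, 205 of 15282 were lost (1.34%, 95% interval 1.17 to 1.54). In the reverse direction, 5 of 9629 regions with at least 10-fold enrichment in both KO libraries were called in neither WT library (0.0519%, 0.0222 to 0.122), and each other division of the 4 libraries gave 0 or 1 such region. Fold enrichments were lower in KO at regions that stayed: at the 14281 retained H3K27ac regions with retained H3K4me3, the median log2 KO over WT fold lay between −0.97 and −0.84 for the 4 pairs of libraries. Loss came to 51.9% at 4- to 10-fold and 82.8% below 4-fold. The strongest lost regions, chosen after their values were seen, included one over a gene end of CYP24A1, the vitamin D 24-hydroxylase (chromosome 20, 54172438 to 54175251; 44.8- and 39.2-fold), which overlapped an MLL4 peak, one inside IGF2BP2 (chromosome 3, 185688977 to 185690047), and one near HNF4G (chromosome 8, 75324210 to 75324993; 19.8- and 22.2-fold). Without H3K4me3, 66.1% of H3K27ac regions were lost, against 7.70% with it. The odds of loss were 8.79 times higher at distal than at promoter regions (8.47 to 9.13; 5.68 without KO replicate 2; 52.9 when distal meant no H3K4me3 peak), 1.85 (1.73 to 1.97) at equal WT fold enrichment, 1.61 with width also equal over regions merged from WT peaks alone, and 1.06 (0.982 to 1.14) in the same comparison among regions without H3K4me3, which no longer excluded 1. Where a lost H3K27ac region had H3K4me1 in WT, H3K4me1 was lost as well in 78.1% of cases, against 26.6% at retained regions, and in 80.1% against 59.6% among regions without H3K4me3. Counted over H3K4me1 regions, loss was 77.7% in all and 93.7% without H3K4me3. Retained H3K27ac regions were also wider (median 2257 bp, against 807 bp for lost ones) and can meet a KO H3K4me1 peak more easily. These shares therefore do not show that the marks were lost together.

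H3K27ac loss was less frequent than in random lists for 3 of the 12 gene lists and more frequent for none (two-sided permutation test, Benjamini-Hochberg adjustment). The random lists were matched on regions per gene but not on fold enrichment or H3K4me3, with which loss varied strongly. The test therefore cannot tell sparing of a list from stronger signal at its genes. AP-1 and immediate early genes lost 108 of 282 regions (38.3%, random median 57.1%, adjusted permutation p = 0.0048). Within this list KLF10 lost 16 of 23, DUSP5, a phosphatase of ERK, 13 of 39 and KLF6 13 of 23, while JUN lost 1 of 7 and gained 4. p53 targets lost 96 of 238 regions (40.3%, random median 52.5%, adjusted permutation p = 0.0216), with IER5 at 13 of 21, CMBL at 7 of 12 and PGPEP1 at 6 of 13. Cell cycle genes lost 80 of 206 (38.8%, random median 54.7%, adjusted permutation p = 0.0272), with RRM2, a subunit of ribonucleotide reductase, at 15 of 30, MCM5 at 13 of 38 and CCND1, cyclin D1, at 10 of 25. The cell cycle call did not hold at −log10 q-values of at least 5 (adjusted permutation p = 0.427) or without KO replicate 2 (adjusted permutation p = 0.125).

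The other 9 lists did not differ from random lists in H3K27ac loss. Colon epithelium and Wnt genes lost 57.4% (adjusted permutation p = 0.851), although single members lost most regions, as NKD1 (40 of 48), EPHB3 (24 of 34) and AXIN2 (22 of 33). The share was 56.8% for TGF-beta, EMT and mesenchyme, 54.8% for hematopoietic and 54.6% for neuronal markers, 54.2% for housekeeping genes, 51.7% for H3K4 methyltransferase complexes, 50.9% for cholesterol and glycolysis and 47.7% for HOX and MEIS genes, each with an adjusted permutation p of 0.851, and 40.7% for interferon and NF-kB genes (adjusted permutation p = 0.475). No list differed from random lists in H3K27ac gain; the lowest adjusted p was 0.54, for cell cycle genes.

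**Figure D3:**
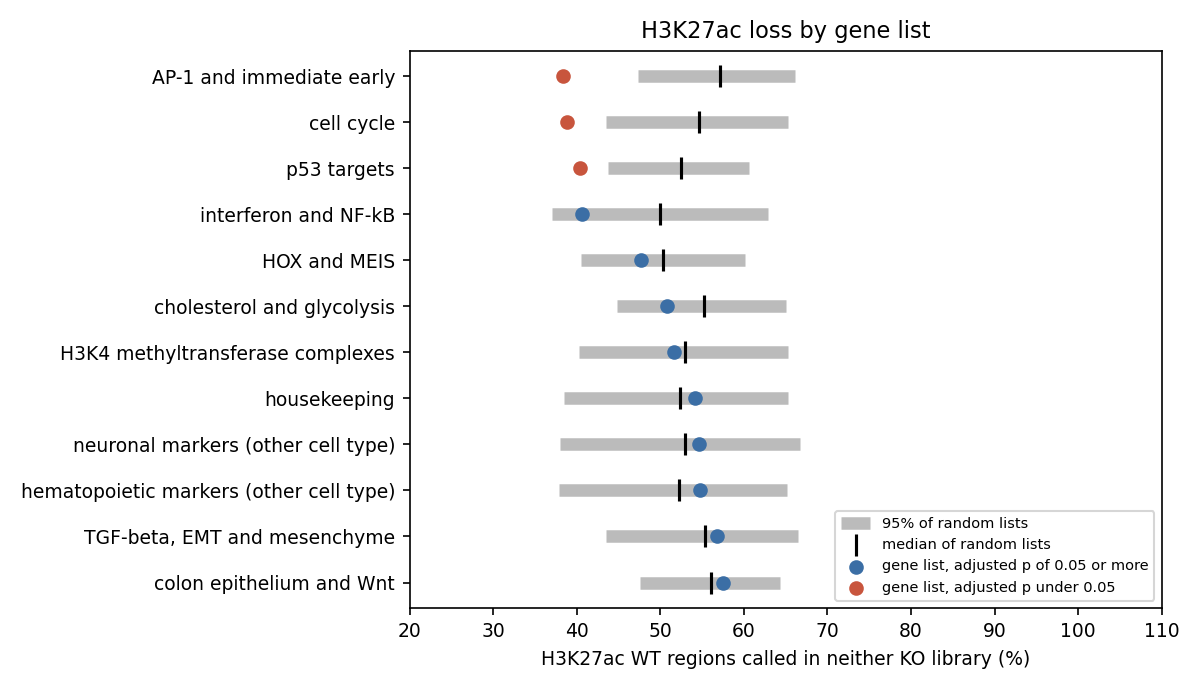
Points give the percentage of H3K27ac WT regions of each gene list that were called in neither KO library, grey bars the central 95% of 10000 matched random lists and ticks their median. AP-1 and immediate early genes (38.3%), cell cycle genes (38.8%) and p53 targets (40.3%) lay below the central 95% of random lists.

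H3K4me3 was largely kept. WT libraries held 20295 ± 887 peaks and KO libraries 19431.5 ± 1476 (SD, n = 2 each; exact permutation p = 0.667), and the direction of the difference turned without KO replicate 2 (log2 KO over WT −0.06 with all libraries and 0.01 without it). Of 17048 WT regions, 912 (5.35%, 95% interval 5.02 to 5.70) were lost and 438 gained, beside 579 for the largest other division of the libraries. With lists of equal length 517 were lost and 499 gained, so little of the excess of loss remained, and at −log10 q-values of at least 5 the counts were 604 and 445. Lost regions numbered 2955 without WT replicate 1, 2234 without WT replicate 2 and 1431 without KO replicate 1. Gained regions numbered 1807 without WT replicate 1, 854 without KO replicate 1 and 1799 without KO replicate 2, against 1022 lost there. The lost regions of highest fold enrichment lay at LRP12 (chromosome 8, 104587918 to 104589892; 75.4 and 74.2), PKIA, a protein kinase A inhibitor (chromosome 8, 78515499 to 78517310; 43.6 and 49.7), near HNF4G (chromosome 8, 75323740 to 75324843; 35.0 and 49.3), at ZNF700 and ZNF69 (34.7 and 177) and over ends of the collagen genes COL4A5 and COL4A6 (32.8 and 50.8). The gained ones lay near JAM3 (22.8 and 19.3), ARHGAP22 (15.4 and 18.1) and RPL29 (13.7 and 14.6), at PCDHB14 (21.3 and 13.8) and inside CCDC187 (13.6 and 20.2).

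Promoters of KMT2D and MDM2 carried H3K4me3 in all 4 libraries. Of 3 H3K4me3 regions assigned to CDKN1A, up to 100 kb away, 2 were lost. No H3K4me3 region assigned to CDKN1A lay within 1 kb of its ends in any library, so this count does not describe its promoter. No gene list differed from random lists in H3K4me3 loss, the lowest adjusted p being 0.286 for colon epithelium and Wnt genes (9 of 45 regions, among them 2 of 3 at KLF5, 1 of 3 at ELF3, 1 of 3 at EPCAM and 1 of 2 at EPHB2), and none in gain (every adjusted p 1). Of the 15520 retained H3K4me3 regions, H3K27ac was present in both WT libraries at 95.9% and in both KO libraries at 92.2%.

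MLL1 was compared as another H3K4 methyltransferase. The WT library held 36933 peaks over 21.4 Mb and the KO library 29072 over 29.8 Mb. Lost regions numbered 18606 (55.4% of WT regions), gained ones 13971 and retained ones 14982. The direction of the difference in peak number depended on the threshold: log2 KO over WT was −0.35 for all peaks and 0.31 at −log10 q-values of at least 5, where 1473 regions were lost and 5747 gained. With lists of equal length the order of the counts turned as well, with 11948 lost and 14639 gained. MLL1 stayed at H3K4me3: 86.3% of the retained H3K4me3 regions held MLL1 in WT, 90.2% in KO and 82.9% in both. Without H3K4me3, 94.2% of MLL1 regions were lost and 92.1% of KO regions were gained.

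The KO-only MLL1 regions of highest fold enrichment lay inside FAM20C (chromosome 7, 204107 to 205686; 62.8), LOC124904701 (56.0), UVSSA (51.2) and ATAD3A (38.2) and at a gene end of SIMC1 (51.8), and all 5 overlapped MLL4 peaks of the WT library. The WT-only ones lay on RN7SL4P (37.1), on chromosome 21 at the ribosomal RNA pseudogene RNA18SP5 (19.9), near LOC124903317 (14.4) and ABCC2 (14.2) and far from genes on X (13.7). Those on RN7SL4P, at RNA18SP5 and on X overlapped MLL4 peaks too. Over all MLL1 regions, MLL4 peaks lay at 19.1% of KO-only, 5.69% of WT-only and 48.2% of retained ones. At the gene lists, MLL1 loss stood lowest relative to random lists for HOX and MEIS genes (17 of 60 regions, 28.3%, percentile 0.035) and highest for hematopoietic markers (12 of 17, percentile 98.7). MLL1 gain stood highest relative to random lists for neuronal markers (32 of 44, percentile 99.9), where all 10 KO regions of RBFOX3 were gained and all 11 of its WT regions lost, and PAX6 gained 4 of 5, and lowest for AP-1 and immediate early genes (36 of 89, percentile 0.1). At the MDM2 and KMT2D promoters MLL1 was called in both genotypes, with higher folds in KO. They were 8.60 in WT and 43.4 in KO at MDM2, and 16.1 and 70.6 at KMT2D. The median fold over all MLL1 peaks was 4.62 in WT and 6.48 in KO.

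p53 binding was compared because the design names cooperation of MLL4 with p53. Of 50 p53 target genes, 36 had a p53 peak within 5 kb of the gene in all 4 libraries, 1 in none (TRIM22, singled out after its values were seen), none in WT alone and 3 in both KO libraries alone: RRM2B, BTG2 and KITLG. A nearby p53 peak was not particular to targets. Of genes that carried H3K4me3, 69.0% of targets and 73.3% of others had p53 in both WT libraries within 5 kb. Among the targets, FDXR had p53 peaks in every library (fold enrichment 13.6 and 37.3 in WT, 8.70 and 13.3 in KO), as did BBC3, which encodes the apoptosis factor PUMA (20.02 and 34.1 in WT, 9.09 and 12.2 in KO), both singled out after their values were seen. The CDKN1A gene held p53 peaks in every library, with highest folds of 7.72 and 10.3 in WT and 5.94 and 11.4 in KO, as did MDM2 (8.96 and 10.4 against 8.10 and 11.4). The background level recovered for the p53 lists was 0.324 and 0.419 in WT and 0.958 and 0.575 in KO. These folds therefore rest on different backgrounds in the 2 genotypes. The p53 targets lost 1 of 59 p53 regions (at APAF1; adjusted permutation p = 0.14). Housekeeping genes lost 9 of 26, the highest share (34.6%, adjusted permutation p = 0.0624), and no list passed the test for p53 loss or gain, the lowest adjusted p for gain being 0.414.

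The p53 lists held 34578 ± 2753 peaks in WT and 43610 ± 26358 in KO (SD, n = 2 each; exact permutation p = 1), the 2 KO libraries holding 24972 and 62248. Lost regions numbered 3152 (12.7% of WT regions) and gained ones 3594, beside 2849 for the largest other division of the libraries. With lists of equal length the order turned, with 4165 lost and 2865 gained. Without KO replicate 2, the longest list, the direction of the peak number turned (log2 KO over WT 0.19 with all libraries and −0.47 without it), with 10377 lost and 6489 gained regions. Gained regions numbered 32279 without KO replicate 1, and lost ones 6686 without WT replicate 1 and 7708 without WT replicate 2. The direction also turned at −log10 q-values of at least 5 (−0.42), where 5498 regions were lost and 1631 gained, and 5530 were gained with at least 50% of a peak covered. Gained p53 regions overlapped H3K4me3 in 63.7% of cases and lost ones in 4.28%. Of the retained H3K4me3 regions, 52.95% held p53 in both WT libraries and 68.9% in both KO libraries.

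Of the 10 p53 regions of WT with the highest −log10 q-values, 9 lay on chromosome 21 between 8207606 and 8443693, 6 of them on ribosomal RNA genes, and 1 lay elsewhere. The 5 lost p53 regions of highest fold enrichment all lay in the same span, up to 60.4- and 86.4-fold. The gained ones lay at GTF2H2C (13.3 and 13.3), at TAF15 (11.9 and 11.8), at PRR19 and PAFAH1B3 (11.7 and 13.3) and on the small nucleolar RNA genes SNORD3A (15.3 and 12.7) and SNORD3D (11.7 and 17.1).

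MLL4 and p53 shared many regions. Of H3K27ac regions called in both WT libraries, 53.2% of those bound by p53 also held an MLL4 peak, against 11.1% of the others (odds ratio 9.08, 95% interval 8.76 to 9.42), and the odds ratio was 4.83 (4.64 to 5.03) at equal H3K27ac fold enrichment and 5.505 with lists of equal length. Region width was not held equal in these values, and wider H3K27ac regions can overlap more peaks. With width held equal, alone or together with fold enrichment, the odds ratio kept its direction. Its 95% interval still excluded no association. The widths there include KO peaks. MLL4 was present within 5 kb of 37 of the 42 p53 target genes that carried H3K4me3 (88.1%), against 84.6% of other such genes (odds ratio 1.35, 0.527 to 4.40). p53 in both WT libraries was present at 29 of these 42 (69.0%) and at 73.3% of the others (odds ratio 0.814, 0.410 to 1.71).

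Before adjustment, regions bound by MLL4 lost H3K4me1, H3K27ac, H3K4me3, p53 and MLL1 peaks less often than other regions. MLL4 peaks lay at 6.44% of lost and 27.9% of retained H3K4me1 regions (odds ratio 0.178, 95% interval 0.171 to 0.185), and at 9.91% of lost and 37.2% of retained H3K27ac regions (0.186, 0.179 to 0.193; 0.116 without WT replicate 1 and 0.365 with lists of equal length). The odds ratio was 0.136 (0.109 to 0.169; 0.240 at −log10 q-values of at least 5) for H3K4me3, 0.230 (0.210 to 0.253; 0.348 without KO replicate 2) for p53 and 0.0649 (0.0605 to 0.0696) for MLL1, where it moved to 0.438 (0.363 to 0.526) at −log10 q-values of at least 5. At equal WT fold enrichment it came to 0.283 for H3K4me1, 0.819 (0.771 to 0.868) for H3K27ac, 0.554 for H3K4me3, 0.259 for p53 and 0.125 for MLL1. Width was then held equal too, over regions merged from WT peaks alone, since merged widths otherwise include KO peaks. The values were 0.495 for H3K4me1, 0.574 for H3K4me3, 0.383 for p53 and 0.243 for MLL1, and the H3K27ac direction turned to 1.18 (1.11 to 1.25). Among regions without H3K4me3 they were 0.851 (0.788 to 0.919) for H3K4me1, 0.517 for p53, 0.142 for MLL1 and 1.34 (1.25 to 1.44) for H3K27ac.

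Regions bound by p53 in WT gave a similar picture. Their odds of loss were 0.0952 (0.0912 to 0.0992) for H3K4me1 and 0.199 (0.191 to 0.206; 0.121 without WT replicate 1 of H3K27ac and 0.404 with lists of equal length) for H3K27ac. For H3K27ac the direction turned to 1.24 (1.16 to 1.33) at equal WT fold enrichment, and over regions merged from WT peaks alone to 1.56 (1.46 to 1.67) with width also held equal and 2.31 (2.12 to 2.52) without H3K4me3. For H3K4me1 the last of these was 0.773 (0.698 to 0.855) and stayed below 1.

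**Figure D4:**
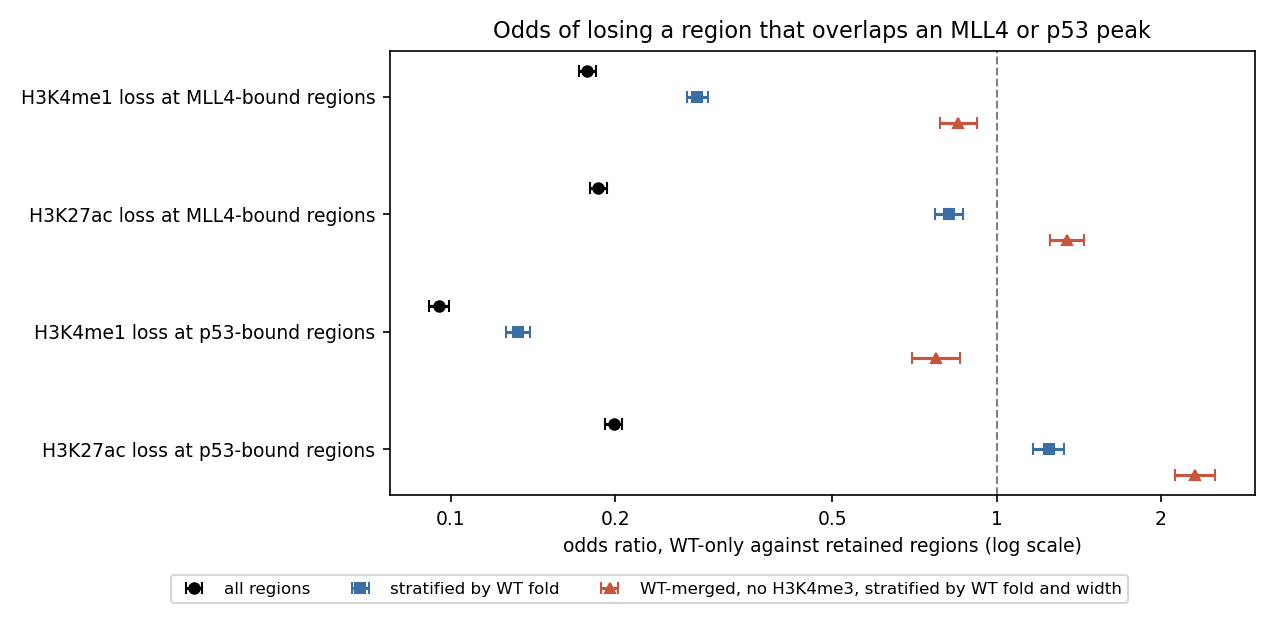
Points are odds ratios on a log scale with 95% intervals for the loss of H3K4me1 or H3K27ac regions that overlap an MLL4 or p53 peak of WT, for all regions, after stratification by WT fold, and for regions merged over WT peaks alone without H3K4me3 and stratified by WT fold and width. The H3K27ac values passed from 0.186 to 1.34 at MLL4 peaks and from 0.199 to 2.31 at p53 peaks.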

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

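The tests of an explanation in this part were chosen after the result was seen, except that the comparison with lists of equal length was fixed before the data were examined. The ratio of shares taken from it was chosen afterwards. Peaks on chromosome Y and on the mitochondrial genome entered no comparison, and the MLL4 library of WT cells held 26 on Y and 5 on the mitochondrial genome, above the 2 and 0 of the KO library. They drew attention as signal outside the chromosomes analysed. The same WT list held 204 times as many peaks elsewhere, and no explanation was tested.

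H3K27ac regions were lost 59066 times and gained 1061 times. A difference in list length does not account for all of it: with lists of equal length the share lost was still 2.46 times the share gained. Loss of whole chromosomes does not either, since every chromosome lost at least 41.2% of its regions. That check does not cover parts of chromosomes. Among regions without H3K4me3, 53.05% were lost on distal 8q, 10q, 16q and 17q (from 120, 100, 80 and 40 Mb to the chromosome end). The share was 84.1% on X and 67.3% elsewhere, and the reason for this difference was not tested. Whether the calling limit alone accounts for the loss stays open. Of regions with at least 10-fold enrichment in both WT libraries 1.34% were lost, above the 0.0519% of the reverse direction. Each other division of the libraries mixes the genotypes, so none shows how a weaker enrichment of both KO libraries would act, and KO folds were lower at retained regions with retained H3K4me3 too (median log2 −0.97 to −0.84). Of regions below 4-fold 82.8% were lost, which the calling limit and a true loss confined to weak enhancers both predict. An effect of the knockout stays open as untested, with 1 input and an unknown number of clones per genotype.

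H3K27ac loss was rarer at MLL4 and p53 peaks in the simple comparison, which held neither strength nor width equal. Weak signal alone would leave an odds ratio of 1 only if fold and width were matched exactly and the targets were called independently. Among regions without H3K4me3 merged over WT peaks alone, the odds ratio was 1.34 at MLL4 peaks and 2.31 at p53 peaks. Fold was matched by decile, as the lower of the 2 WT libraries, and the MLL4, p53 and H3K27ac lists of WT share 1 input. These values therefore cannot set the calling limit aside. For H3K4me1 the value at MLL4 peaks was 0.851, so strength, width and H3K4me3 may account for most of the low odds ratio seen there. A greater need for MLL4 where MLL4 and p53 sit is a candidate explanation for the H3K27ac values and stays a hypothesis, since matching by decile leaves differences inside each decile.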

How the results depend on the processing

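The alternatives that stratify by width or leave out H3K4me3 regions, those with regions merged over WT peaks alone, and the leave-outs of the gene lists, were chosen after seeing the data. Of 224 alternative values, 168 kept their direction and stayed near the main value or on its side of the threshold, 37 counts or values moved, 5 lost their call and 14 reversed. Where no reason is given, the cause was not tested.

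At −log10 q-values of at least 5, which shortens lists by construction, log2 KO over WT was −5.27 for MLL4, −3.59 for H3K4me1, 0.31 for MLL1 (reversed) and −0.42 for p53 (reversed), and 1.03% of MLL4 WT peaks met a KO peak. Lost and gained regions numbered 46744 and 525 for H3K4me1, 33227 and 418 for H3K27ac, 5498 and 1631 for p53, 604 and 445 for H3K4me3 and 1473 and 5747 for MLL1. With lists of equal length the MLL4 share was 6.83%, lost and gained regions numbered 23704 and 17167 for H3K4me1, 9233 and 2756 for H3K27ac, 517 and 499 for H3K4me3, 4165 and 2865 for p53 and 11948 and 14639 for MLL1. The order turned for p53 and MLL1. With at least 50% of a peak covered, 1716 H3K27ac and 5530 p53 regions were gained.

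At equal WT fold enrichment the odds ratio of H3K27ac loss at p53 peaks reversed to 1.24. At equal fold and width it was 1.59, and 1.25 at MLL4 peaks. Among regions without H3K4me3 these were 2.37 and 1.42, and the distal odds ratios, 1.09 for H3K4me1 and 1.03 for H3K27ac, no longer excluded 1. The widths there include KO peaks. With regions merged over WT peaks alone, the value at p53 peaks was 1.27 at equal fold, 1.56 with width and 2.31 without H3K4me3, and at MLL4 peaks 1.18 and 1.34 for the last 2, all reversed. The distal value without H3K4me3 was 1.06 for H3K27ac, which no longer excluded 1, and 1.23 for H3K4me1. The cell cycle list lost its call at −log10 q-values of at least 5 (50.8%) and without KO replicate 2 (50.2%).

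Leaving out 1 library gave log2 KO over WT from −1.65 to −1.13 for H3K27ac, −0.14 to 0.013 for H3K4me3 and −0.47 to 0.85 for p53. The last 2 reversed without KO replicate 2. Lost regions ranged from 65839 to 140822 for H3K27ac, 1022 to 2955 for H3K4me3 and 3605 to 10377 for p53, and gained ones from 1740 to 6128, 503 to 1807 and 4642 to 32279. With 1 library fewer a region must match fewer lists, so counts rise by construction.

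With the replicate number as a replicate block, log2 KO over WT stayed at −1.39 for H3K27ac, −0.06 for H3K4me3 and 0.19 for p53 (exact permutation p 0.5, 0.5 and 1; smallest possible 0.5). Correlations of 0.0113, 0.0667 and 0.00988 over all regions gave no clear sign that the numbers pair libraries. For H3K4me3, 579 regions were called in both replicate 1 libraries alone and 27 in both replicate 2 libraries alone. WT replicate 1 with KO replicate 2 gave 161, and WT replicate 2 with KO replicate 1 gave 84. A pairing of the H3K4me3 libraries therefore stays open. The search for p53 motifs and its alternative were not run, as no genome sequence was used. Read depth is unknown, and with it the number of regions missed near the calling limit in either genotype.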

Other observations

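The regions and genes in this part were chosen after their values were seen, and the values are given without a test of their cause.

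Besides CYP24A1, IGF2BP2 and the region near HNF4G, the 10 strongest lost H3K27ac regions lay inside RASA4B (fold enrichment 43.0 and 26.3 in WT), over a gene end of SLC5A11 (35.0 and 24.3), inside LEMD2 (21.2 and 24.8), COL23A1 (23.3 and 20.5) and CAGE1 (22.9 and 18.7), near CDCA7L (19.0 and 35.5) and near BBS10 (22.4 and 18.4). Those at CYP24A1, SLC5A11 and COL23A1 overlapped MLL4 peaks, and none of the 10 overlapped p53 in both WT libraries. Near HNF4G, H3K27ac and H3K4me3 were lost at overlapping positions. The strongest gained regions lay over a gene end of KLRC2, a receptor of natural killer cells (chromosome 12, 10435183 to 10436259; 18.1 and 19.1 in KO), near IGSF23 (14.8 and 19.1) and inside or near LYPLAL1 (12.0025 and 17.1; 10.7 and 16.2).

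At the short RNA genes with the strongest MLL4 peaks, MLL1 was called as well. Its fold enrichment in WT was 87.0 at RN7SL1 (chromosome 14, gene 49586580 to 49586878), 48.0 at RN7SK (chromosome 6, gene 52995620 to 52995951), 52.1 at RN7SL2, 37.1 at RN7SL4P and 16.4 at RPPH1. In KO it was 8.80, 8.44, 8.67, not called and 9.36. At a ribosomal RNA region on chromosome 21 (8433643 to 8436985) p53 had folds of 154 and 287 in WT and 26.5 and 43.2 in KO. RN7SL1, RN7SK and RN7SL4P had no p53 peak in any of the 4 libraries. RN7SL2 had p53 peaks in WT replicate 1 (5.52) and KO replicate 1 (4.16), and RPPH1 in KO replicates 1 (3.47) and 2 (6.52).

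The 5000 strongest p53 peaks of a library make up a different share of each list. Of these, 39.5% and 43.2% overlapped H3K4me3 in WT and 91.3% and 87.7% in KO; over all peaks of a library these shares were 33.2% and 35.1% in WT and 55.6% and 29.2% in KO, where replicate 2 lay below both WT libraries. Of the 50 p53 target genes, those within 5 kb of one of the 5000 strongest peaks numbered 11 and 11 in WT (odds ratio against other genes 1.15 and 1.04) and 27 and 18 in KO (3.29 and 1.62; 95% intervals 1.82 to 6.02 and 0.858 to 2.99). The strongest KO peaks lay mostly at H3K4me3, and the other genes in this comparison include ones without it. Among genes that carried H3K4me3, p53 regions called in both KO libraries lay within 5 kb of 38 of 42 target genes. This held for 85.4% of the other such genes (odds ratio 1.63, 0.586 to 6.29). Of p53 regions in both KO libraries, 93.9% overlapped H3K27ac regions of WT and 1.57% no histone peak, against 80.4% and 8.81% in WT. Of p53 regions in both WT libraries on X, 41.1% were lost, and on any other chromosome at most 17.5%. Among p53 regions without H3K4me3, distal 8q, 10q, 16q and 17q held 394 of the 1304 gained ones. They held 133 of the 3017 lost and 783 of the 5664 retained ones. X held 5 of these gained, 133 of the lost and 14 of the retained regions. Gains and losses of p53 regions thus differed between parts of the genome, and the reason was not tested.

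Of retained H3K4me3 regions, 7.33% held MLL1 in KO alone and 3.40% in WT alone.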
